A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

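RNA of 2 Saccharomyces cerevisiae wine strains, UCD522 (high sulfide production per the labels) and P29 (low sulfide production), was compared on 2 two-colour arrays of different platforms. On both arrays P29 was in channel 1 (Cy5 on array 1, phycoerythrin on array 2) and UCD522 in channel 2 (Cy3), per the labels. No dye was swapped, so a dye effect on a gene cannot be separated from a strain effect. The labels count 2 biological replicates per strain and give 1 hybridisation per platform, and each array was taken as 1 replicate of the same contrast. Every log2 ratio below is UCD522 over P29.

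Array 1 carried spotted cDNA. Cells were kept in an RNA stabilising solution before hot acidic phenol extraction, and cDNA was labelled indirectly, per the labels' protocols. Its deposited values were spot and local background intensity at both wavelengths, read with GenePix Pro 5.1.0.19 on a GenePix 4000B scanner with no normalization, per the file headers. The percent of saturated pixels of each spot was deposited with them, per the file headers. Array 2 carried oligonucleotides of 25 bases synthesised in place, with up to 5 probes per gene. Its cells were snap frozen and ground, RNA was purified on a kit column, and biotin-labelled cRNA was stained, per the labels' protocols. The deposited values of array 2 were the mean signal intensity of each probe in both strains, without a background column, and any correction made before deposit was not given in the sources used here. The labels name the Merlin software without its role.

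The authors also deposited 1 processed log2 ratio per gene and array, used here as an alternative. For array 1 these log2 values correlated across genes with the log2 ratio of the background-subtracted scanner intensities (Pearson's r = 0.993), and 94.6% of them lay within 0.001 of it. They were therefore uncentred, with a median of -0.33 over 5796 genes. For array 2 the correlation was 0.705 with the unnormalized ratio and 0.797 with the normalized ratio computed here. The median was 0.07 over 6022 genes, the direction followed the labels' strains, and the authors' background correction and normalization for array 2 stayed unknown. Neither table had a column that matched no sample (0 columns).

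The background was corrected with limma's normexp method and an offset of 50, on all spots or probes, and each array's ratios were normalized by loess fitted on open reading frames only. On array 1 a spot was kept when at least 1 channel lay more than 2 background SDs above the mean local background. Of 558 empty spots, 4 passed this rule, and 3780 spots of 3604 open reading frames were kept among 6511 spots of 6179 open reading frames. On array 2, 12 probes with a UCD522 signal of 0 were left out and genes above the 20th percentile of mean log2 intensity were kept, 4825 of 6032. Saturated spots were kept, and 11 spots of array 1 had saturated pixels. Spots and probes of a gene were averaged on the log2 scale. The median SD was 0.11 between spots of a gene on array 1 and 0.42 between probes of a gene on array 2. Precision was limited by the number of arrays.

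Genes were matched by systematic name to a symbol table of assembly R64, which named 5671 open reading frames of array 1 and 5528 of array 2. The others kept their systematic names. No genome build is named in the files, so no coordinates are given. Genes on both arrays (2969) were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom per gene, the estimated prior degrees of freedom were infinite and the prior SD was 0.56, so every gene received the same standard error of 0.39. Consequently the test took no account of how far the 2 arrays disagreed on a gene. The p-values rest on 2 arrays, 1 per platform, with no dye swap, and the spread between them holds both culture and platform differences. A fold was to be given as a bound only for a gene not above background in one strain on both arrays, which held for no gene named in the text. On array 2 a strain's channel counted as not above background at or under the 20th percentile of its mean log2 signal over genes. Ratios with such a channel on 1 array are inexact, and those genes are listed with the calls.

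Of 32 gene lists, 29 had at least 5 genes on both arrays and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it, but with 1 residual degree of freedom they could hardly call any list. The median of each list was also placed, per array, among 10000 random lists of the same size matched on intensity in 20 bins, as a description of that array. The gene lists, tests, filters and most alternatives were fixed before the data were examined. The rule for named genes was fixed with them. It took the 12 genes per direction with the largest smaller absolute log2 ratio among genes of the same sign on both arrays, counting a near-identical family as 1 name. For called lists, and for the thiamine and sulfate assimilation lists, it added up to 4 members in the prevailing direction and up to 2 in the other.

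The tests were tested on simulated data of 2969 genes on 2 arrays with 200 changed genes. They called 35 of 67 genes changed by 1 on the log2 scale, 67 of 67 changed by 2, 66 of 66 changed by 3, and 5 of 2769 unchanged genes. A shifted list was called, and 0 of 100 unshifted lists were. The simulated genes varied independently of each other, and the unshifted lists were drawn at random. The list result therefore does not show how often lists whose genes move together on an array are called falsely. The simulated genes of an array shared 1 normal spread, equal to that array's own, with no platform-specific effects on single genes.

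The alternatives were no background correction, plain subtraction, median centring, loess per printing block, no filter, a filter on both channels, an equal spread of both arrays, the authors' processed values, the brightest probe or spot, near-identical families left out, an intensity trend with robust spread, a size threshold of 1.5-fold, and each array alone. Leaving out a group of similar spots on array 1, a detection limit from the 99th percentile of empty spots and medians of probes or spots were added after seeing the data. Bootstrap standard errors came from 1000 draws over genes or probes. They measure the spread between genes or probes and hold no spread between cultures or arrays. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.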

Results

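Transcripts of the wine yeast strains UCD522 and P29 were compared during fermentation of pasteurised grape juice. The labels describe UCD522 as a high producer and P29 as a low producer of sulfide, the compound that gives wine a rotten egg odour. Both strains were grown in parallel in bottles of 1 L at 18 ºC and sampled when fermentation was fastest. RNA of both strains was hybridised together on 1 spotted cDNA array (array 1) and on 1 array of short oligonucleotides (array 2). On array 1 the median signal of open reading frames above local background was 202 units in UCD522 and 250 in P29, over median backgrounds of 360 and 163. On array 2 the median probe signal was 2569 in UCD522 and 2799 in P29, beside mean signals of 2181 and 2474 over 4 blank probes. After filtering, 2969 genes were measured on both arrays.

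The first comparison asked which genes differed between the strains. Genes of thiamine (vitamin B1) biosynthesis and uptake had the highest mean log2 ratios of UCD522 over P29. THI4 (YGR144W), which makes the thiazole part of thiamine, had a mean log2 ratio of 2.93 ± 2.10 (SD, n = 2), a 7.62-fold difference, with 1.44 on array 1 and 4.42 on array 2. THI5 (YFL058W), THI12 (YNL332W), THI13 (YDL244W) and THI11 (YJR156C), near-identical genes of pyrimidine precursor synthesis, had mean log2 ratios of 4.15, 3.93, 3.50 and 3.01. The arrays differed in size, with 5.50 on array 1 and 2.79 on array 2 for THI5, and 5.45 and 2.40 for THI12. The values were 4.06 and 2.94 for THI13, and 2.78 and 3.23 for THI11. THI22 (YPR121W), related to pyrimidine kinases of the pathway, had 3.47, SNZ3 (YFL059W) of the vitamin B6 synthesis family had 2.53, and PHO3 (YBR092C), an acid phosphatase that acts on thiamine phosphates, had 1.86. All 8 passed limma's test with Benjamini-Hochberg adjustment, with adjusted p-values from 4.1e-22 (THI5) to 0.00032 (PHO3).

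Genes outside the thiamine list that were higher in UCD522 on both arrays included PDC5 (YLR134W), a pyruvate decarboxylase, at 1.43 on array 1 and 2.07 on array 2 (mean 1.75 ± 0.45, SD, n = 2, limma adjusted p = 0.0012). The aryl-alcohol dehydrogenase genes AAD14 (YNL331C) and AAD3 (YCR107W) had mean log2 ratios of 2.50 and 1.64, with limma adjusted p-values of 6.7e-08 and 0.0036. YAL065C had 2.86 on array 1 and 1.20 on array 2 (mean 2.03, limma adjusted p = 4.6e-05), and only 3 of its 5 probes on array 2 were higher in UCD522. PET18 (YCR020C) and the transporter gene THI73 (YLR004C), both further members of the thiamine list, had mean log2 ratios of 2.28 and 1.38. Their limma adjusted p-values were 1.9e-06 and 0.034. PET18 had 3.21 on array 1 and 1.35 on array 2, and THI73 had 1.19 and 1.57. ALT1 (YLR089C), an alanine transaminase, had 1.30 on array 1 and 1.20 on array 2 and did not pass limma's test (adjusted p = 0.094).

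Fewer genes were called higher in P29. PCK1 (YKR097W), the phosphoenolpyruvate carboxykinase of gluconeogenesis, had a mean log2 ratio of -2.07 ± 0.84 (SD, n = 2), a 4.20-fold difference (limma adjusted p = 3e-05). FBP1 (YLR377C), the gluconeogenic fructose bisphosphatase, had -1.56, and ERG3 (YLR056W), a sterol desaturase, had -1.50, with limma adjusted p-values of 0.0072 and 0.012. YNR064C had -1.51 and the hexose transporter gene HXT4 (YHR092C) had -1.47, with limma adjusted p-values of 0.012 and 0.016. PIR3 (YKL163W), a cell wall glycoprotein gene, had -1.32 on array 1 and -1.33 on array 2 and just missed the threshold (limma adjusted p = 0.051). The mean log2 ratios were -1.24 for GSC2 (YGR032W, a glucan synthase), -1.24 for HSP12 (YFL014W, a stress protein), -1.23 for PST1 (YDR055W, a cell wall protein), -1.13 for SRL1 (YOR247W), -1.13 for OM14 (YBR230C) and -0.97 for YIM1 (YMR152W). None of these 6 passed limma's test, with adjusted p-values from 0.10 (GSC2) to 0.52 (YIM1).

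**Figure D1:**
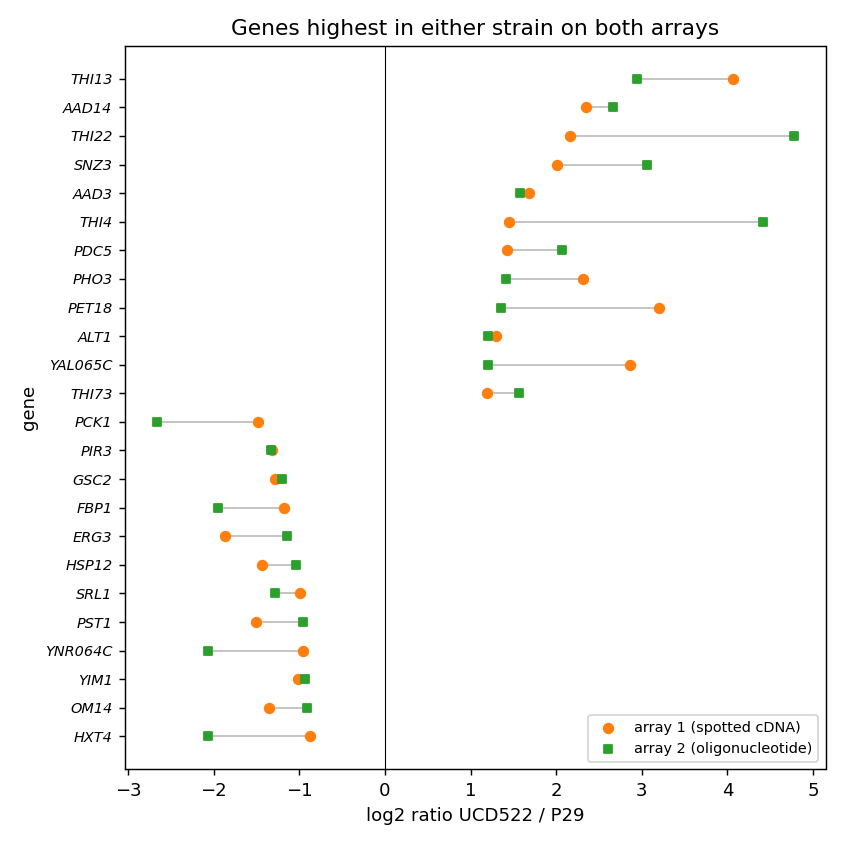
Log2 ratio of UCD522 over P29 on array 1 (circles) and array 2 (squares) for the 12 genes per direction with the largest smaller ratio of one sign. The pairs lie close for ALT1 (1.30 and 1.20) and PIR3 (-1.32 and -1.33) and far apart for THI4 (1.44 and 4.42).

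Over all 2969 genes, limma called 43 with Benjamini-Hochberg adjustment, 30 higher in UCD522 and 13 higher in P29 (5 and 0 with an equal spread of both arrays). Of these, 14 belonged to the thiamine list and 29 did not. By limma, 143 genes had an unadjusted p under 0.05, 74 of them higher in UCD522. That is no more than 2969 tests at this threshold would give without any difference. Only 21 of the 43 were at least 2-fold different in one direction on both arrays. Some calls rested on 1 array, as for the flocculin gene FLO9 with 4.69 on array 1 and 0.06 on array 2, and the alcohol dehydrogenase gene ADH4, singled out after its values were seen, had opposite signs (4.78 and -1.34). Every gene had the same standard error of 0.39 in this fit. The count depended strongly on the processing, from 0 calls with no background correction or the brightest probe or spot to 55 with the detection limit from empty spots. The spot of THI13 on array 1 had 51% of its pixels saturated, the 2 spots of THI11 on that array gave 0.65 and 4.91, and the near-identical THI, SNZ and HXT genes cannot be fully separated by their probes.

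The ratios of some named genes are inexact because 1 channel was not above background on 1 array. On array 1 this was the P29 channel for AAD3, YAL065C, UGA2 and BAT2, and the UCD522 channel for ERG25, HXT5 and BNA7. On array 2 it was the P29 channel for THI73, FLO9 and AAD10, and the UCD522 channel for HXT4 and FBP1. Their mean log2 ratios and folds carry the same uncertainty, as does that of THI13 with its saturated spot.

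The second comparison counted genes at least 2-fold different on each array. On array 1, 68 genes were higher in UCD522 and 55 in P29, and on array 2, 188 and 187. Among the genes on both arrays, 23 were 2-fold higher in UCD522 on both, where 2.95 would be expected from independent lists. Most of the 23 belonged to the thiamine list, among them near-identical genes. Much of the excess is therefore that of 1 group of genes. The others of the 23, such as AAD14, PDC5 and SSU1, were not set beside an expectation of their own. The count by itself does not show a general agreement of the arrays. For P29 the count was 6 (PCK1, PIR3, GSC2, FBP1, ERG3 and HSP12), where 2.21 would be expected. The balance depended on the settings, with 41 in UCD522 and 42 in P29 at 1.5-fold, and 16 and 27 with the authors' processed values. The latter are uncentred on array 1, with a median of -0.41 over all genes, which moves counts toward P29. Their counts therefore do not measure a balance between the strains. The opposite directions held 3 genes (UCD522 on array 1 and P29 on array 2) and 4 genes (the reverse), where 2.65 and 2.46 would be expected. These are counts by size on single arrays and carry no test.

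The third comparison asked how far the arrays gave the same ratios across genes. Cytosolic ribosomal protein genes, 115 on both arrays, had a median log2 ratio of 0.43 on array 1 and -0.38 on array 2, and 102 of them had opposite signs. Ribosome biogenesis genes (24) had medians of 0.35 and -0.27. Relative to all genes on both arrays, both groups kept these signs on each array under all 13 alternatives examined. Neither list was called by camera (Benjamini-Hochberg adjusted p = 0.99 and 0.71).

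Across the 2969 genes, which are not independent replicates, Pearson's r between the arrays was 0.0765 and Spearman's rho was -0.0841. Two-sided permutation tests with 1e+05 permutations gave p = 0.00012 for r and p = 1e-05 for rho, the smallest possible, and Benjamini-Hochberg adjustment over both gave 0.00012 and 2e-05. The same sign on both arrays was found for 46.1% of genes. Without the thiamine list r was -0.0366 and rho -0.102. The correlation was lost for rho with loess per printing block (-0.013, permutation p = 0.47) and for r without near-identical families (0.0205, permutation p = 0.27).

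**Figure D2:**
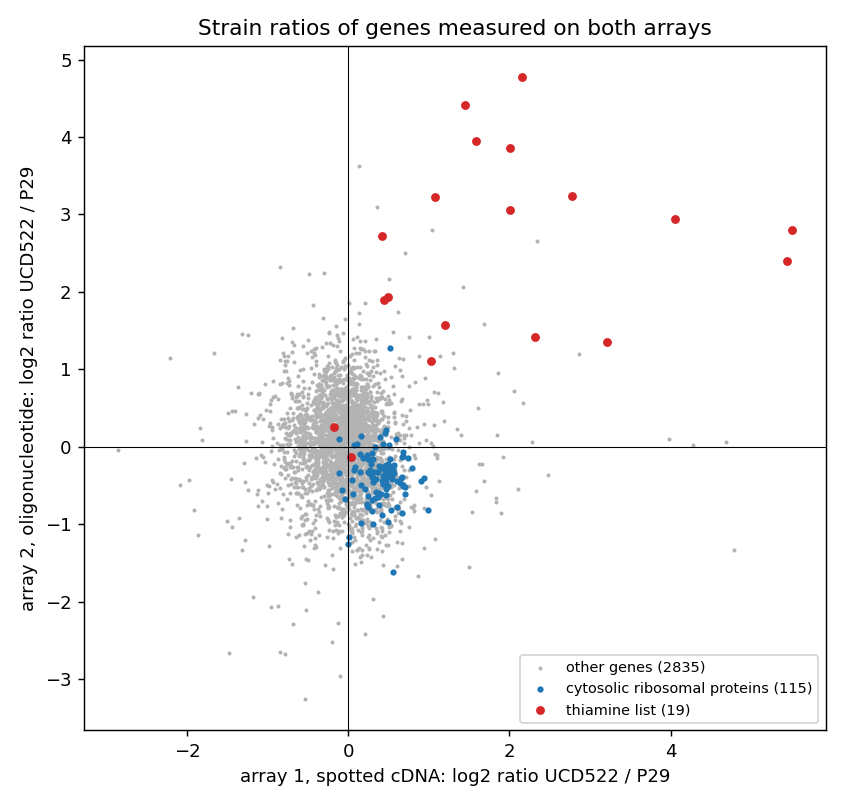
Log2 ratio of UCD522 over P29 on array 1 (horizontal) against array 2 (vertical) for 2969 genes, with the thiamine list (19 genes) and cytosolic ribosomal proteins (115 genes) marked. Thiamine genes fill the upper right, with 17 of 19 higher in UCD522 on both arrays, and 102 of 115 ribosomal protein genes have opposite signs.

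The fourth comparison asked whether gene lists differed between the strains. Of 22 listed genes of thiamine biosynthesis and uptake, 19 were on both arrays, and 17 of these were higher in UCD522 on both. The exceptions, named after their values were seen, were the regulator genes THI3 (-0.17 and 0.26) and PDC2 (0.04 and -0.13). The list's median log2 ratio was 1.59 on array 1 and 2.73 on array 2, above all 10000 intensity-matched random lists on each array (percentile 100). Limma called 14 of the 19 over all genes and 17 adjusted over the list alone. Camera called the list (Benjamini-Hochberg adjusted p = 2.2e-106, adjusted p = 0.84 with an estimated correlation). THI2 (1.56), SNO2 (3.31) and SNO3 (2.12) were measured on array 2 alone.

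The list of sulfate assimilation and sulfite export holds the pathway that produces sulfide. It also holds genes that act otherwise, such as SSU1 and MET17, so a test for a common direction is not a test of sulfide formation. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.47, adjusted p = 0.97 with an estimated correlation). SSU1 (YPL092W), the sulfite efflux pump gene, had log2 ratios of 1.00 and 1.42 (mean 1.21 ± 0.30, SD, n = 2, limma adjusted p = 0.12), and it was the 1 member that passed when adjusted over the list alone. MET16, the reductase gene of activated sulfate, had 0.28 and 0.61, the sulfate permease gene SUL2 had 0.17 and 0.26, and MET1, for synthesis of the sulfite reductase cofactor, had 0.13 and 0.89. MET17, whose enzyme fixes sulfide into homocysteine, had -0.46 and -0.39. None of these 4 passed limma's test (adjusted p = 1). Of 13 genes on both arrays, 4 were higher in UCD522 on both, 1 was lower and 8 had opposite signs. The median over the genes of each array was -0.07 on array 1 (percentile 28.5 of random lists) and 0.42 on array 2 (percentile 97.5). SUL1 (0.73), MET4 (0.62), MET30 (0.55) and MET31 (0.42) were measured on array 2 alone, and CBF1 (-0.21) on array 1 alone.

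Nitrogen catabolite repressed genes, which are transcribed when preferred nitrogen sources run short, had a median log2 ratio of 0.52 over 22 genes. The members with the largest ratios on both arrays were UGA2 (1.31 and 1.02) and UGA1 (0.96 and 0.89) of gamma-aminobutyrate use, the aminotransferase gene BAT2 (0.98 and 0.60) and the glutamine synthetase gene GLN1 (1.18 and 0.58). The amino acid permease gene AGP1 had -0.16 and -0.88, and none of these 5 passed limma's test, with adjusted p-values of 0.16 (UGA2) or more. Over all genes limma called 2 members, and 3 adjusted over the list alone. Camera called the list (Benjamini-Hochberg adjusted p = 3.4e-06, adjusted p = 0.84 with an estimated correlation). The difference rested on array 2 (0.81), since the median on array 1 was -0.02.

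Vitamin B6 and NAD biosynthesis had a median of 0.43 over 11 genes, with 7 higher in UCD522 on both arrays and medians of 0.31 on array 1 and 0.15 on array 2. NPT1 (0.68 and 1.13) and BNA4 (0.66 and 0.91) of NAD synthesis, SNZ1 (0.40 and 0.64) and the pyridoxal phosphate gene PDX3 (0.31 and 0.78) led it, and BNA7 had -0.15 and -0.01. Limma called none of the 11, nor any adjusted over the list alone, and camera called the list narrowly (Benjamini-Hochberg adjusted p = 0.040, adjusted p = 0.84 with an estimated correlation). Ester and higher alcohol formation had a median of 0.29 over 14 genes (0.14 on array 1 and 0.34 on array 2), and camera called it (Benjamini-Hochberg adjusted p = 0.0032, adjusted p = 0.84 with an estimated correlation). AAD3 and PDC5, described above, were the 2 called members, also when adjusted over the list alone. BAT2 (0.98 and 0.60) and AAD10 (0.51 and 0.60) had positive ratios, and the ethyl ester synthase genes EHT1 (-0.40 and -0.09) and EEB1 (-0.08 and -0.02) had negative ones. Median centring and loess per printing block each ended the vitamin list's call, and the filter on both channels ended the ester list's call and turned its median on array 1. That median was also negative with median centring (-0.039) and with the authors' processed values (-0.34). These 2 settings lowered the median of all genes on array 1 to -0.12 and -0.41.

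Hexose transporter genes had a median of -0.71 over 6 genes, 4 of them lower in UCD522 on both arrays. The other 2 had opposite signs, HXT1 (0.55 and -0.44) and HXT3 (-0.94 and 0.64), and were named after their values were seen. Over all transporters measured on an array the median was smaller in size. It was -0.23 on array 1 (11 genes, percentile 7.86 of random lists) and -0.35 on array 2 (9 genes, percentile 4.9). HXT4 (-0.87 and -2.06) was the 1 called member, also when adjusted over the list alone, and HXT7 (-0.83 and -0.92), HXT5 (-0.41 and -1.27) and HXT6 (-0.83 and -0.35) did not pass limma's test. Camera called the list (Benjamini-Hochberg adjusted p = 0.0014, adjusted p = 0.84 with an estimated correlation), and the call was lost with no filter on dim spots (camera adjusted p = 0.16). Ergosterol biosynthesis and sterol uptake had a median of -0.45 over 24 genes, 17 of them lower in UCD522 on both arrays. ERG3 was the 1 called member, also when adjusted over the list alone. ERG25 (-0.73 and -1.44) and ERG5 (-1.07 and -0.70) of the late pathway, and the squalene epoxidase gene ERG1 (-0.64 and -1.17), did not pass limma's test. The early pathway genes IDI1 (0.34 and 0.28) and ERG8 (0.46 and 0.19) had positive ratios, and that of ERG8 turned with the authors' processed values. Camera called this list (Benjamini-Hochberg adjusted p = 1.9e-05, adjusted p = 0.84 with an estimated correlation).

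Cell wall genes, flocculins and mannoproteins had a median of -0.37 over 28 genes, and 19 were lower in UCD522 on both arrays. PIR3, GSC2 and PST1 led the list, followed by CCW14 (-0.72 and -1.04), while FLO9 (4.69 and 0.06) and the chitin synthase gene CHS3 (0.05 and 0.34) had positive ratios. Limma called 2 members higher in UCD522, FLO9 and its near-identical relative FLO1, the latter named after its values were seen (4.28 and 0.03), and none higher in P29. Adjusted over the list alone, 5 were higher in P29 and 2 in UCD522. Camera called the list lower (Benjamini-Hochberg adjusted p = 0.010, adjusted p = 0.84 with an estimated correlation), and the authors' processed values ended the call (camera adjusted p = 0.099).

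The list of hypoxic genes of the DAN/TIR group, many of them coding for mannoproteins of oxygen-starved cells, had a median of -0.39 over 14 genes. TIR3 (-0.53 and -3.26) and DAN1 (-0.20 and -2.53) were called by limma (adjusted p = 0.00023 and 0.038), and 3 members passed adjusted over the list alone. ANB1 had -0.28 and -0.25. Not every member is a hypoxic gene, since HYP2 (-0.30 and -0.52) is the counterpart of ANB1 in cells with oxygen and ROX1 codes for a repressor of hypoxic genes. Camera called the list (Benjamini-Hochberg adjusted p = 0.00026, adjusted p = 0.84 with an estimated correlation), with a median of -0.74 on array 2 and of -0.15 on array 1, where it turned with loess per printing block. The call was lost with the brightest probe (-0.16, adjusted p = 0.18). The related PAU family had a median of 0.30 on array 1 and -0.94 on array 2, with 18 of 19 genes of opposite sign and PAU21 positive on both (0.40 and 0.17), though not with the authors' processed values. Limma called no PAU gene, also adjusted over the list alone. Camera called the family lower (Benjamini-Hochberg adjusted p = 0.040, adjusted p = 0.97 with an estimated correlation), a call that several alternatives ended and plain subtraction turned.

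**Figure D3:**
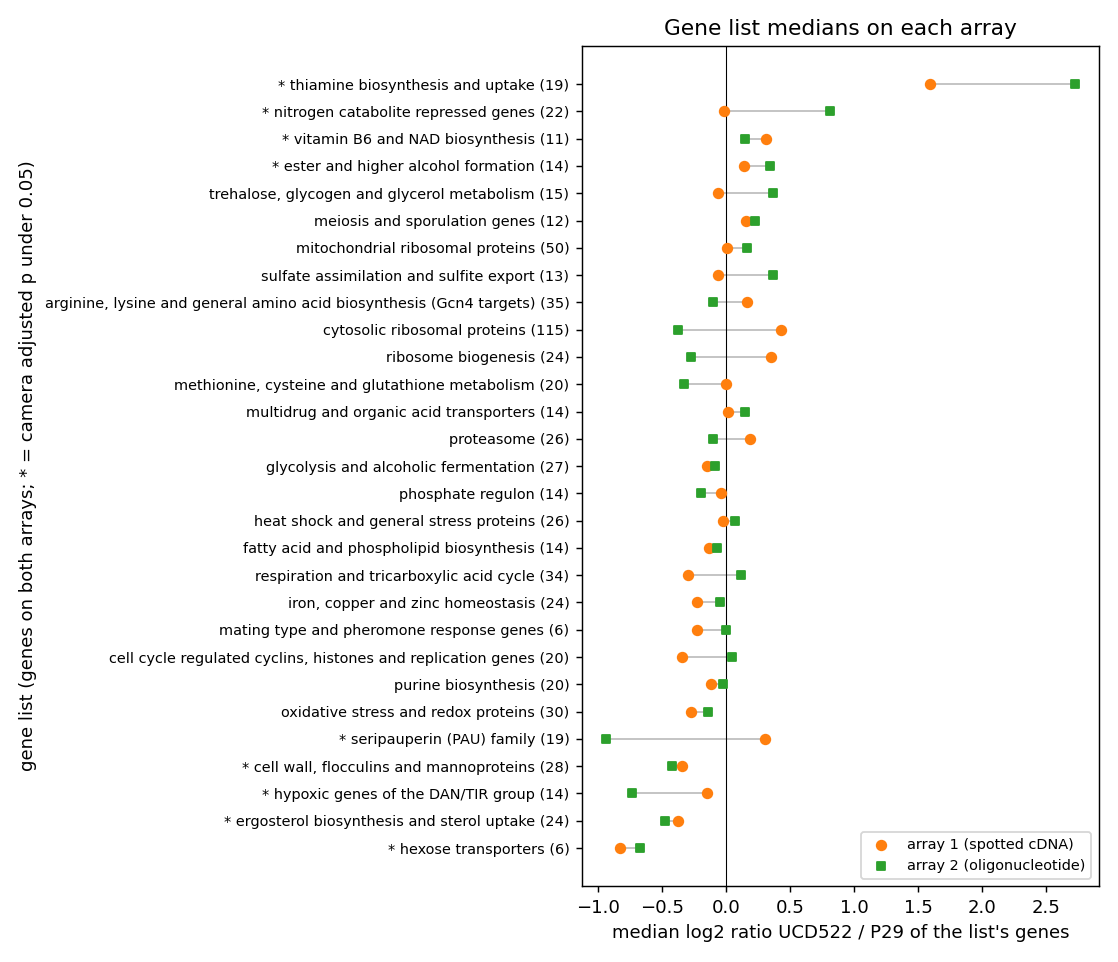
Median log2 ratio of UCD522 over P29 of the tested gene lists on array 1 (circles) and array 2 (squares), with the number of genes in parentheses and an asterisk on the 9 lists called by camera. The thiamine list stands apart at 1.59 and 2.73, and the PAU family (0.30 and -0.94) and cytosolic ribosomal proteins (0.43 and -0.38) lie on both sides of 0.

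Camera thus called 9 of 29 tested lists with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.84. By fry, which asks whether a list's genes moved one way, no list was called (lowest Benjamini-Hochberg adjusted p = 0.49). Camera with an estimated correlation and fry both rested on 1 residual degree of freedom, so they could hardly call any list. Their lack of calls therefore decides nothing about the lists. Before adjustment, the thiamine list had p = 0.041 with an estimated correlation and the ergosterol list had p = 0.033 by fry. The lists of trehalose, glycogen and glycerol metabolism and of cell cycle genes came nearest to a call among the others, both with a camera adjusted p of 0.12 after Benjamini-Hochberg adjustment. Percentiles of list medians among random lists, over the genes of each array, follow for arrays 1 and 2 in turn. They were 46.6 and 100 for nitrogen, 98.85 and 74.4 for vitamin B6 and NAD, and 97.95 and 94.4 for esters. They were 0.07 and 1.8 for ergosterol, 0.17 and 0 for cell wall genes, 18.1 and 0 for DAN/TIR, and 99.63 and 0 for PAU.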

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

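Both signals lie outside the measurement of yeast genes, were looked at after the data were seen, and were not weighed further. On array 1, 23 of 103 spots under names that are not systematic open reading frame names (22.3%) lay more than 2 background SDs above local background in at least 1 channel, against 4 of 558 empty spots (0.717%). On array 2, a set of 5 probes not named for a yeast gene was brighter than every blank probe (lowest signal 4117, highest blank 3340) and had a mean log2 ratio of 0.89 (SD 0.51 over probes), higher in UCD522.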

How the results depend on the processing

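Leaving out a group of spots of array 1 with similar ratios, the limit from empty spots and medians of probes or spots were chosen after seeing the data. The thiamine list was called by camera under all 14 alternatives with a test, with medians from 1.30 (near-identical families left out) to 2.48 (equal spread), and the nitrogen and ergosterol lists were called under the same 14. The sulfate list was called under none of them, with a median of -0.21 with the authors' processed values, which shift all genes of array 1 to a median of -0.41. Median centring shifted them to -0.12. Of 768 values of named genes under other settings, 110 lost the threshold, 15 gained it and 8 changed sign, and the rest kept direction and side. The cause was not tested for any change below, unless fewer genes or arrays are named.

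The 43 calls (30 and 13, UCD522 first) became 0 (0 and 0) with no background correction and with the brightest probe or spot, 10 (9 and 1) with plain subtraction, 17 (14 and 3) with no filter, 28 with both channels above background (8 in P29, 2349 genes tested), 5 (5 and 0) with equal spread, 27 with the authors' processed values (18 in UCD522), and 9 (9 and 0) with medians of probes or spots. Calls higher in P29 became 21 with the limit from empty spots. All 10, 5 and 9 calls of plain subtraction, equal spread and medians were among the 43. Lists called became 14 with an intensity trend and robust spread.

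The 2-fold counts on both arrays (23 and 6) became 11 and 1 with no background correction, 14 and 3 with plain subtraction, 41 and 42 at 1.5-fold, 15 in UCD522 without near-identical families, and 16 and 27 with the authors' processed values. On array 1 (68 and 55) they became 43 and 36 with no background correction, 178 and 289 at 1.5-fold, 39 and 366 with the authors' values, and in P29 95 with median centring and 101 with equal spread. On array 2 (188 and 187) they became 49 and 17 with no background correction and with plain subtraction, which leaves array 2 uncorrected, 656 and 601 at 1.5-fold, 107 and 96 with equal spread, 495 and 334 with the brightest probe, and 457 in UCD522 with the authors' values. Loess per block left array 2 as it was. The authors' values of array 1 are uncentred, with a median of -0.41 over all genes, which by itself moves their counts toward P29.

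The PAU family's median was 0.067 with plain subtraction, of the other sign, and its call was lost with no background correction (-0.031), no filter (-0.22), equal spread (-0.14), the authors' values (-0.35), the brightest probe (-0.13) and the limit from empty spots (-0.22). Calls were also lost for vitamin B6 and NAD with median centring (0.34, adjusted p = 0.074) and loess per block (0.40, adjusted p = 0.066), with values from 0.00079 upwards under the other settings, for hexose transporters with no filter (-0.053), for esters with both channels above background (0.093), for the DAN/TIR group with the brightest probe (-0.16) and for cell wall genes with the authors' values (-0.63). The camera adjusted p reached 0.97 for the PAU family and 0.18 for the DAN/TIR group. Spearman's rho was -0.013 with loess per block and Pearson's r 0.0205 without near-identical families. Among named genes, the sign changed for BNA7 with loess per block (0.025) and the brightest probe (0.055), for SUL2 (-0.15) and ANB1 (0.10) with the brightest probe, and for MET16 (-0.20), PDX3 (-0.029), ERG8 (-0.042) and PAU21 (-0.49) with the authors' values.

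With 1 array left out there is no residual degree of freedom and no test. The ranges over the arrays alone were 60 to 146 genes 2-fold higher in UCD522 and 50 to 131 in P29. Medians ranged over 1.59 to 2.73 for thiamine, -0.063 to 0.36 for sulfate, 0.15 to 0.31 for vitamin B6 and NAD, -0.017 to 0.81 for nitrogen, -0.83 to -0.68 for hexose transporters, -0.48 to -0.38 for ergosterol, 0.14 to 0.34 for esters, -0.74 to -0.15 for DAN/TIR, -0.94 to 0.30 for PAU and -0.42 to -0.34 for cell wall genes. These medians are over the genes on both arrays. No paired analysis was possible because the series has 1 group of ratios. On array 2, median signals near those of blank probes limit the ratios of dim genes.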

Other observations

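The genes of this paragraph were chosen after their values were seen. Outside the naming rule, limma with Benjamini-Hochberg adjustment also called 2 enzymes of non-fermentable carbon use higher in P29, the isocitrate lyase gene ICL1 (-0.84 and -2.65, adjusted p = 0.0012) and the alcohol dehydrogenase gene ADH2 (-1.91 and -0.82, adjusted p = 0.038). THI74, which was not in the thiamine list, was called higher in UCD522 (0.71 and 2.50, adjusted p = 0.0048). The nitrogen-regulated genes DAL7 (0.36 and 3.10) and GAP1, the general amino acid permease gene (0.51 and 2.16), were called with limma adjusted p-values of 0.0013 and 0.049 and differed mainly on array 2. FCY22 (0.13 and 3.62, with the P29 channel of array 1 not above background) and YOR387C (3.98 and 0.11) were called on the strength of 1 array.

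Genes among the 15 outermost open reading frames of each chromosome arm, a list fixed before the data were examined, numbered 193 on both arrays. Without the thiamine list, 28.9% of 187 were at least 2-fold different on at least 1 array, against 10.1% of genes elsewhere, a difference that was not tested. Limma with Benjamini-Hochberg adjustment called 13 of them, 4 were 2-fold higher in UCD522 and 1 in P29 on both arrays, and their median mean log2 ratio was -0.03.

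For the 3 patterns weighed next, the tests of thiamine genes away from chromosome ends, of cross-hybridization and of a local stain were chosen after the result was seen. Thiamine genes were higher in UCD522 on both arrays. Extra copies of chromosome ends in UCD522 cannot be the whole cause, because members away from the ends had a median mean log2 ratio of 1.57 (SE 0.37, 13 genes). Such copies predict nothing for these members, so their values say nothing about the members at the ends. Extra copies of other regions were not tested. Mismatches of P29 transcripts to the short probes of array 2 are argued against as the whole cause. There 92.6% of 95 probes (SE 3.62) were higher in UCD522, and the list's median was 1.59 on the spotted cDNA of array 1. The share of probes does not show whether mismatches added to the size on array 2. For members at the ends, extra copies could still contribute, since 11 neighbouring genes had a median of 0.29 (SE 0.22), too imprecise to decide and including AAD14 (2.50), whose value had been seen. Cross-hybridization stays open for members of near-identical families, and the 10 members outside such families had a median of 1.30 (SE 0.35). A strain difference in thiamine regulation or in the uptake of thiamine from the juice also stays open and was not tested.

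The log2 ratios of the arrays were opposed or unrelated across most genes. Smooth trends on intensity, coding length and probe GC content are argued against, because rho was -0.109 (SE 0.0196, 2866 genes) after they were removed and -0.0912 before. Ribosomal genes as the whole carrier stay open, with rho = -0.0387 (SE 0.0193) without them. Differences between printing blocks of array 1 may carry the negative sign, since rho was -0.013 with loess per block, but they leave the ratios unrelated. Handling, RNA extraction and labelling differed between the arrays with 1 array per method, so these and differences between the cultures cannot be told apart.

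On array 1, 96 printed positions in 8 blocks had similar ratios, with a median log2 ratio of -0.67 (interquartile range 0.153, against 0.464 elsewhere). Their brightness varied less than elsewhere but was not uniform (interquartile range of log2 intensity 0.84, against 1.66). The same genes had a median of 0.11 on array 2, and 0 of the 86 on both arrays were called (limma, 45 calls over all genes without these positions and 43 with them). Neighbouring spots had a median ratio higher by 0.55 (SE 0.0305). The positions were picked for their similar ratios, so this difference cannot decide on a local stain, which stays open. One DNA shared by these spots is a candidate explanation that stays open, because the brightness of the 86 genes had a rho of 0.211 between the arrays (SE 0.111), against 0.395 for other genes. The bound set beforehand, within 2 SEs of the other genes' rho, was met and would have counted against it, but it was wrongly chosen, since with this SE the value also lies within 2 SEs of 0, and no biological explanation was tested.

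A hypothesis was that the P29 cells were at a later stage of fermentation, with more glucose-repressed transcripts, since PCK1, FBP1, ICL1 and ADH2 were higher in P29. It was tested on 37 other glucose-repressed genes, chosen as genes whose ratios had not been looked at, of which 16 were on both arrays. However, ALD4 and SPS19 belonged to gene lists tested earlier, so their values had already entered list results. The median log2 ratio of the 16 genes was -0.27 on array 1 (SE 0.11) and -0.31 on array 2 (SE 0.24). Of the 16, 11 were lower in UCD522 on both arrays, among them JEN1 (-0.52 and -2.11) and MLS1 (-0.51 and -0.75). Against it, 2 genes were higher in UCD522 on both, IDP3 (0.097 and 0.45) and FDH1 (0.095 and 0.14), and 3 had opposite signs, SPS19 (-0.23 and 1.08), DLD1 (-0.23 and 0.061) and PEX11 (-0.48 and 0.10). Both medians have the direction that a later stage may give, but neither lay under the bound of -0.3 by more than its SE. These SEs are over genes and hold no spread between cultures. The hypothesis was left undecided.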
